A study of Mus musculus with 29 samples.

How the data were processed

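The files held 29 scanner tables of one-colour Agilent mouse arrays (62976 spots each, 59305 of them not controls, 55681 distinct probes) and the authors' series matrix of 39430 probes. Per the labels, RNA was taken up in TRIzol LS from cells sorted on a FACSAria, and Cy3 target was made from 0.1 µg RNA with the Low Input Quick Amp kit. Per the file headers, the intensity of each spot was read from the scan by Agilent Feature Extraction 11.5.1.1, the version named in the submitters' files, which subtracted background and gave the processed signal that was deposited. The log2 values in the series matrix were deposited by the authors, and how they were scaled is not given in the sources used here. Their column medians ran from -3.18 to -2.33. In the columns that match, the median difference from the scanner signal scaled to the array's 75th percentile was 0.125 to 0.216, so their scale is close to the one used here. Of the 29 columns 27 match their scanner files, and the 2 columns of mouse MC221 at day 7 match none. These 2 correlated at 0.9865 (EGFP) and 0.9945 (TdTomato) with their own files. With the closest other file the correlations were 0.9932 and 0.9950. Which arrays belong to these 2 samples is therefore not settled. The scanner files were used and the series matrix served as an alternative.

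The signal was turned into log2, the array's 75th percentile was subtracted, and spots marked by the scanner software as non-uniform, or as far from the other spots of their probe, were set aside. A probe was kept if it was well above background on at least 3 of the 29 arrays, which left 38196 probes. Probes were named through their RefSeq accessions: 26582 had 1 symbol, 29099 had none, 0 had several, and 20145 genes were named. Of the probes past the filter 20454 had a symbol, and the brightest probe of each gene gave 15628 genes with 50 missing values. Probes without a symbol were left out of all gene counts, and no column belonged to an unknown sample.

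Genes were tested with limma 3.58.1 in R 4.3.3, in a fit of 8 group means to all 29 samples with Benjamini-Hochberg adjustment at 0.05. Limma's moderated errors share variance across genes and groups, which is how a group of 2 arrays can be tested. The 13 comparisons are each later day against day 0 in each population, TdTomato against EGFP at each day, and the interaction of both at each later day. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

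Groups of genes were 30 fixed lists, 22 of biology and 8 of cell types, with 860 members written from general knowledge before the data were examined and 14 not on the array. They cover the slit diaphragm and foot process, podocyte transcription factors, the glomerular basement membrane, podocyte injury, focal adhesion and actin, p53 targets, immediate early genes, the integrated stress and unfolded protein response, heat shock, cytosolic ribosomal proteins, translation factors and ribosome biogenesis, the cell cycle, NF-kB and chemokines, interferon-stimulated genes, MHC class I, TGF-beta and matrix, growth factors, regulated cell death, oxidative stress, cholesterol synthesis, the respiratory chain and complement. The cell type lists hold markers of glomerular endothelium, mesangium and smooth muscle, parietal epithelium, proximal tubule, distal nephron, myeloid cells, lymphocytes, and erythrocytes and platelets. Lists were tested with camera of limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The estimates ran from 0.07 to 0.76, so p-values at the preset correlation can be too small. Counts adjusted over the list alone use the members as the only tests.

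Genes were named by a rule set before the data were examined. It names Nphs1, Podxl, Synpo, Wt1 and Des, the 6 largest changes in each direction for a later day against day 0, the 4 largest for the other comparisons, and at most 4 called members per list. A gene named for a largest change had to be well above background on every array of the higher group. Outside the interactions, the samples of both groups also had to show no overlap. This was not asked of the genes fixed by name or of the list members. Clone and model names were passed over. The largest changes are given in full for EGFP at days 4 and 7 and from the top of the list elsewhere. A few genes that the rule names are not reported here.

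EGFP and TdTomato samples of the same mouse form a replicate block. After group means were removed, the correlation of both samples of a mouse ran from 0.04 in MC823 to 0.64 in MC122, and the consensus correlation within mice was 0.596. The mouse was entered as a fixed term for TdTomato against EGFP and the interactions, and as a random block for the later days, as alternatives. The other alternatives set before the data were examined were normexp background correction, quantile normalization, no filter and a strict filter on dim probes, the authors' values, the mean of a gene's probes, only the groups compared in the fit, a threshold of 2-fold, the slide as a block and leaving out each sample. Normexp was planned on the mean spot signal, which the files lack, and used the median signal with an offset of 50. After the data were examined 2 were added: both MC221 arrays left out, and genes within the carry-over share left out.

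In a self-test, values were simulated with the mean and spread of each of the 15628 genes and no group differences, and 200 genes were given a known change. Between 16.5% and 52% were called at a change of 1 log2 and between 65% and 87% at 2 log2, the lowest for the interactions. The sign was wrong for 0 genes, and 1 to 14 false calls were made. The simulated values were independent between genes and samples, whereas in the data the consensus correlation within mice was 0.596. The number of false calls in the real data can therefore differ.

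The carry-over share is the median rise in EGFP as a percentage of the rise in TdTomato over genes above background on no day 0 array that rose by over 6 log2 in TdTomato and were not called in EGFP. A list's percentile was read from 10000 random lists matched in 20 bins of day 0 level. The bounds for carry-over and for other cells in the sort were made stricter after their values had been seen, which left carry-over at day 1 and endothelial and myeloid cells at day 4 open. The direction of genes on a slide was read from genes called without the arrays of that slide, a check added after the results were seen.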

Results

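The series holds 29 one-colour arrays of podocyte RNA from 16 male C57BL/6J mice aged 8 weeks, 4 mice at each of days 0, 1, 4 and 7 after an injection of the immunotoxin LMB2 (25 ng per gram of body weight, per the labels). LMB2 joins an antibody fragment against human CD25 to a Pseudomonas exotoxin that blocks translation elongation, and it kills cells that carry human CD25. Podocytes were sorted by fluorescence into a TdTomato and an EGFP population. From what is known of the study, and not from the labels, TdTomato marks the podocytes that carry human CD25 and EGFP marks podocytes of the same glomeruli that lack it. The TdTomato population therefore asks about direct injury by the toxin and the EGFP population about injury that reaches untargeted neighbours. EGFP had n = 4, 3, 4 and 4 and TdTomato had n = 4, 4, 4 and 2 at days 0, 1, 4 and 7, and 13 mice gave both populations. Day 0 mice are different animals from the later ones. The protocol in the labels names a heminephrectomy before the injection, and whether day 0 mice had it is not given in the sources used here. If they did not, changes from day 0 in either population could also reflect the surgery.

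Between 48.2% and 65.5% of the spots lay well above background on each array, no spot was saturated, and the correlation across genes between arrays of a group was 0.956 to 0.988. The number of arrays limits the precision. In all, 15628 genes were tested. Values are log2 signals relative to the 75th percentile of the array. Errors are standard errors of limma, p-values are Benjamini-Hochberg adjusted values of limma for genes and of camera for gene lists, and a list's shift is its median change relative to the median of all genes. Where no array of the lower group was well above background, a fold is given as a lower bound taken from the detection level, in the words "at least".

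**Figure D1:**
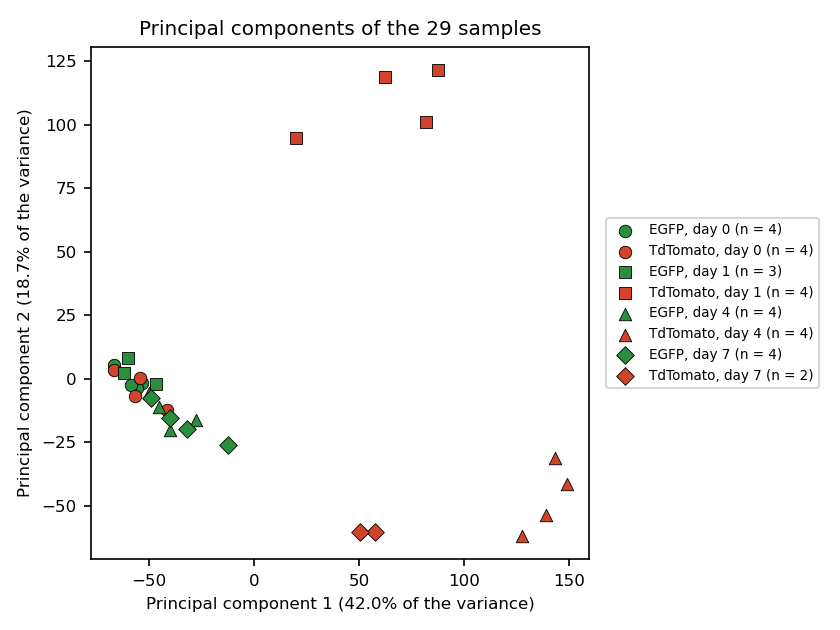
Each point is 1 of the 29 arrays, placed by its score on the first (x axis, 42.0% of the variance) and second (y axis, 18.7%) principal component of 15628 genes, with colour and shape for population and day. EGFP arrays of all days and TdTomato arrays of day 0 lie below 0 on the first component and all later TdTomato arrays above it, where MC541 at day 1 scored 19.9 on the first component against 62.6 to 87.5 for the other TdTomato arrays of that day.

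Before injection the TdTomato and EGFP populations were compared to see whether they start alike. Limma called 0 of 15628 genes different at day 0 (n = 4 and 4), with 74 genes at an unadjusted p under 0.05, and Nphs1, the slit diaphragm protein nephrin, stood at 7.61 ± 0.22 (SD) in TdTomato and 7.54 ± 0.31 in EGFP. Markers of other kidney cells passed camera as lists, but at the preset correlation only. The estimated correlation was 0.60 in the tubule list and 0.64 in the endothelial list against the preset 0.01. Camera p-values at the preset can therefore be too small for them. Markers of the proximal tubule were higher in TdTomato by 1.27 (camera adjusted p = 4.2e-15; adjusted p = 0.87 with an estimated correlation). Markers of glomerular endothelium were higher by 0.48 (adjusted p = 2.8e-05; adjusted p = 0.96 with an estimated correlation), with 0 members called in either list. Within the 4 slides these medians ran from 0.07 to 2.58 and from -0.09 to 1.70, and the endothelial call ended without EGFP MC122 (0.16) or TdTomato MC742 (0.25). Smaller shifts were 0.06 for cytosolic ribosomal proteins, 0.06 for the respiratory chain and -0.08 for TGF-beta and extracellular matrix genes, each past the test at the preset correlation only (adjusted p = 0.96 with an estimated correlation for all 3). Ribosomal and respiratory genes turned below 0 with normexp background correction and without TdTomato MC122 (-0.04 and -0.03), and ribosomal genes also without EGFP MC753 (-0.02). The ribosomal call also ended without EGFP MC731 (0.05) or TdTomato MC742 (0.01). The respiratory call ended without any 1 of EGFP MC731, MC742 or MC753 or TdTomato MC742 (0.01 to 0.05). Both ended with quantile scaling, no filter or only the groups compared in the fit. The matrix call ended with normexp and without TdTomato MC122 or either MC753 array (-0.07 to -0.03). For mesangial and smooth muscle markers the median was above 0 and the test pointed down, at adjusted p = 0.87; it passed without EGFP MC122 (-0.27) or EGFP MC742 (0.17).

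In EGFP podocytes 1 day after injection, very little changed. Of 15628 genes 4 were higher and 0 lower (n = 3 and 4). Kcnk10, a potassium channel, rose 6.87-fold (log2 2.78 ± 0.45, adjusted p = 0.011) and Epha8, an ephrin receptor, rose at least 9.43-fold (adjusted p = 0.033). The other 2, Pkp1 and Dner, were chosen for naming after their values were seen. The podocyte genes Nphs1 (-0.29 ± 0.18), Podxl (-0.13 ± 0.31) and Wt1 (-0.06 ± 0.23) did not pass. All 4 called genes were among those that rose in TdTomato, where Epha8 rose at least 874-fold, and their rise in EGFP was 0.519% to 0.871% of the rise in TdTomato. Without day 0 MC122 or MC753 the count was 2, without day 0 MC731, day 0 MC742 or day 1 MC542 it was 0, and with normexp background correction or only the groups compared in the fit it was 0. With the slide as a block 3 were higher and 1 lower. With slide 1 held out, 7 genes were called on the others and 71.4% of them moved the same way on it; with slide 3 or 4 held out 0 were called. Epha8 (3.44 to 4.58) and Kcnk10 (2.53 to 2.76) lost their calls without any 1 of MC122, MC731 or MC742 of day 0 or MC125 or MC542 of day 1, and Epha8 also without day 0 MC753.

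No member of any list was called at day 1 in EGFP, and the lists that passed camera did so as small or variable shifts. Markers of glomerular endothelium were lower by -1.25 (adjusted p = 3.3e-07; adjusted p = 0.51 with an estimated correlation), with slide medians from -2.64 to -0.13. Mesangial and smooth muscle markers were lower by -1.04 (adjusted p = 8.5e-08; adjusted p = 0.43 with an estimated correlation). Proximal tubule markers were higher by 1.1 (adjusted p = 4.7e-06; adjusted p = 0.51 with an estimated correlation), a call that ended without day 1 MC541 (0.37). Beside them stood immediate early genes at -0.31, glomerular basement membrane genes at -0.27 and TGF-beta and extracellular matrix genes at -0.28, with adjusted camera p of 1.5e-06, 2.7e-06 and 5.5e-05. With an estimated correlation their adjusted p values were 0.43, 0.28 and 0.51. Also lower were MHC class I (-0.28, adjusted p = 0.0012), interferon-stimulated (-0.24, adjusted p = 0.004), focal adhesion (-0.09, adjusted p = 0.0096) and growth factor genes (-0.25, adjusted p = 0.0099). So were podocyte transcription factors (-0.07, adjusted p = 0.025) and the unfolded protein response (-0.17, adjusted p = 0.028). With an estimated correlation focal adhesion genes had adjusted p = 0.54 and the other 5 had adjusted p = 0.51. All 6 calls ended without day 0 MC742 (-0.19 to -0.09). The respiratory chain was higher (0.09, adjusted p = 0.045; adjusted p = 0.90 with an estimated correlation). That call ended with the mouse as a random block (0.07), the slide as a block (0.05) and normexp (0.04), and without day 1 MC125 (0.01).

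At day 4 the EGFP podocytes began to depart from day 0. There were 87 genes higher and 6 lower (n = 4 and 4). Among the injury markers S100a6, a calcium-binding protein, rose 7.33-fold (2.87 ± 0.43, adjusted p = 0.00058) and Timp1, an inhibitor of matrix proteases, 4.96-fold (2.31 ± 0.33), and Psat1, an enzyme of serine synthesis, rose 3.31-fold. Des, the intermediate filament protein desmin, stood at 1.08 ± 0.26 and missed the threshold at adjusted p = 0.056 (it passed without day 0 MC122, at 1.20, and with the mouse as a random block), while Nphs1 (-0.06 ± 0.17) and Podxl (0.02 ± 0.28) did not move. Among the other rises were those of Thbs4, a matrix glycoprotein (at least 86.3-fold), Crct1, a gene of the epidermal differentiation complex (at least 65.2-fold), Epha8 (at least 35.1-fold) and P2rx7, an ATP-gated channel (66.4-fold, 6.05 ± 0.40). Also higher were the sperm protamine Prm1 (23.6-fold, above background on 1 of 4 day 0 arrays) and the collagen Col22a1 (at least 5.70-fold). The genes that fell most were Creg2 (3.90-fold, -1.96 ± 0.39, adjusted p = 0.013) and the transferrin receptor Tfrc (3.09-fold, -1.63 ± 0.27, adjusted p = 0.0015).

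The rises of Thbs4, P2rx7, Prm1, Col22a1 and Epha8 in EGFP were 1.30%, 1.65%, 0.595%, 0.562% and 0.483% of their rises in TdTomato at day 4. The median was 0.495% (5th to 95th percentile 0.136% to 1.36%) for 118 genes that were silent at day 0, rose strongly in TdTomato and were not called in EGFP, and P2rx7 lay above that range. For Crct1, S100a6, Timp1, Psat1 and Tagln the rise in EGFP lay above 4 times that share. In all, 62 of the 87 genes lay above it and 48 reached at least the TdTomato level. The calls of Epha8, Prm1 and Col22a1 ended with normexp background correction, and that of Creg2 ended without day 0 MC731, day 4 MC692 or day 4 MC822 (-1.91 to -1.68).

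As groups, few lists moved in EGFP at day 4. Of the injury markers 2 of 23 measured members rose (4 adjusted over the list alone). Of the focal adhesion and actin genes 2 of 40 did (4 adjusted over the list alone), the smooth muscle protein Tagln (3.44-fold, a call that ended without day 0 MC731 or day 4 MC822, 1.49 to 1.69) and Flna (without day 0 MC731, MC742 or MC753 or day 4 MC151, MC822 or MC823 its call ended, 0.84 to 1.09). Neither list passed camera (adjusted p = 0.06 for both). Both did with the mouse as a random block (0.13 and 0.12). Both also did without day 0 MC742, day 4 MC151 or day 4 MC823, the injury list also without day 0 MC753 (0.01 to 0.25) and the focal adhesion list also without day 4 MC692 (0.10 to 0.17). Cholesterol synthesis genes shifted by 0.17 (adjusted p = 0.0069; adjusted p = 0.69 with an estimated correlation), and 1 of 25 rose. The respiratory chain shifted by 0.13 (adjusted p = 0.0033; adjusted p = 0.95 with an estimated correlation), a call that ended without day 0 MC731 (0.09) or day 4 MC151 (0.04). Heat shock genes shifted by -0.39 (adjusted p = 6.6e-05; adjusted p = 0.69 with an estimated correlation), with slide medians from -0.71 to 0.08 and 0 of 17 called. Endothelial markers shifted by -0.38 (adjusted p = 0.023; adjusted p = 0.95 with an estimated correlation), a call that ended under normexp or quantile scaling and without day 0 MC742, day 4 MC151 or day 4 MC692 (-0.34 to -0.09).

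With each slide held out in turn, 94.3% to 100% of the genes called on the others moved the same way on it, and with the slide as a block the count was 277 (250 higher, 27 lower). It was 44 without day 0 MC731, 51 without day 4 MC822, 59 without day 4 MC823, 55 with normexp background correction and 28 when only the groups compared entered the fit.

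By day 7 the EGFP podocytes carried a broad injury response, with 834 genes higher and 300 lower (n = 4 and 4). Des rose 11.1-fold (3.48 ± 0.26, adjusted p = 1.7e-09). Crct1 rose at least 1457-fold, the fibrillar collagen Col5a3 303-fold (8.24 ± 0.45), S100a6 169-fold (adjusted p = 1.8e-11), Thbs4 at least 45.7-fold, the matrix metalloproteinase Mmp10 62.6-fold and the citrullinating enzyme Padi4 56.7-fold. The largest falls were smaller, 6.37-fold for Shisal1 (-2.67 ± 0.46), 4.81-fold for the adrenergic receptor Adra2c (-2.27 ± 0.27), 4.24-fold for Pabpn1l, 4.21-fold for the potassium channel Kcna6, 3.66-fold for Fitm1 and at least 1.94-fold for the muscarinic receptor Chrm1. Nphs1 (-0.48 ± 0.17, adjusted p = 0.088), Synpo, the actin-associated protein synaptopodin (-0.25 ± 0.14, adjusted p = 0.34), Wt1 (-0.38 ± 0.21, adjusted p = 0.34), and Podxl (0.01 ± 0.28) did not pass, although Nphs1 passed without MC221 (-0.59).

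The groups that rose in EGFP at day 7 were those of injury, the cytoskeleton, inflammation and matrix. Of 23 injury markers 10 rose and 0 fell (11 adjusted over the list alone), among them Timp1 (54.2-fold, 5.76 ± 0.33), the chaperone clusterin, Clu (21.3-fold), and the urokinase receptor Plaur (17.7-fold). The list shifted by 1.04 (adjusted p = 1.4e-10; adjusted p = 0.0086 with an estimated correlation). Of 40 focal adhesion and actin genes 18 rose and 0 fell (23 adjusted over the list alone). Among them were the calponin Cnn1 (at least 14.7-fold), Tagln (24.1-fold), Cav1 (9.93-fold, above background on 2 of 4 day 0 arrays) and the actin crosslinker Flna (9.11-fold). That list shifted by 0.68 (adjusted p = 3.6e-16; adjusted p = 0.021 with an estimated correlation), and its slide medians were 0.76 to 0.83. Of 29 NF-kB and chemokine genes 17 rose and 0 fell (18 adjusted over the list alone), for a shift of 1.03 (adjusted p = 2.8e-14, and adjusted p = 0.06 with an estimated correlation). Among them were Icam1 (22.3-fold, above background on 2 of 4 day 0 arrays), Cxcl10 (21.0-fold) and Csf1 (17.3-fold). Of 36 TGF-beta and extracellular matrix genes 17 rose and 0 fell (18 adjusted over the list alone), with the growth factor genes Tgfb2 (18.3-fold) and Tgfb3 (17.9-fold), for a shift of 0.70 (adjusted p = 1.4e-10; adjusted p = 0.079 with an estimated correlation).

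Further lists shifted less. Interferon-stimulated genes had 5 of 31 higher and shifted by 0.35 (adjusted p = 0.0021; adjusted p = 0.43 with an estimated correlation), with the guanylate-binding protein Gbp2 up 2.38-fold. Regulated cell death genes had 6 of 29 higher (12 adjusted over the list alone) and shifted by 0.26 (adjusted p = 0.0026; adjusted p = 0.26 with an estimated correlation), with the death receptor Fas up 4.12-fold and Bid up 3.46-fold. Cholesterol synthesis genes had 4 of 25 higher (5 adjusted over the list alone) and shifted by 0.16 (adjusted p = 0.0091; adjusted p = 0.26 with an estimated correlation), with the squalene epoxidase Sqle up 3.63-fold. Targets of p53 had 6 of 24 higher (7 adjusted over the list alone), with Plk2 up 11.1-fold, and shifted by 0.16 (adjusted p = 0.032; adjusted p = 0.43 with an estimated correlation), a call that ended with the slide as a block, no filter, the mean of probes or only the groups compared, and without MC122 of day 0 (0.12). Of the stress and unfolded protein response genes 4 of 26 rose and 3 fell, Psat1 rising 20.6-fold, and the list did not pass (adjusted p = 0.47). The cell cycle list did not pass either (adjusted p = 0.076) unless day 0 MC753 or day 7 MC943 was left out (0.26 to 0.28), although cyclin D1, Ccnd1, rose 10.4-fold. Oxidative stress genes (2 of 19 higher, adjusted p = 0.29) and complement genes (2 of 19 higher, adjusted p = 0.82) did not pass. Basement membrane genes (4 of 20 higher, shift 0.29, adjusted p = 0.044; adjusted p = 0.58 with an estimated correlation) lost their call with no filter or the mean of probes, and without day 0 MC122, day 0 MC731 or day 7 MC791 (0.24 to 0.35). MHC class I genes (3 of 15 higher, 1 lower, 7 and 2 adjusted over the list alone, shift 0.49, adjusted p = 0.044; adjusted p = 0.61 with an estimated correlation) lost theirs with no filter, the mean of probes or the slide as a block, and without day 0 MC122, MC731 or MC753 or day 7 MC791 or MC943 (0.41 to 0.50).

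The podocyte lists moved down by little in EGFP at day 7. Of 35 slit diaphragm and foot process genes 0 rose and 2 fell, Sema3g (2.62-fold) and Thsd7a (1.95-fold), and the list shifted by -0.13 (adjusted p = 0.044; adjusted p = 0.61 with an estimated correlation). That call ended with quantile scaling, the authors' values, the mean of a gene's probes or only the groups compared, and without day 0 MC122, day 0 MC742, day 7 MC221 or day 7 MC943 (-0.16 to -0.10). Of 18 podocyte transcription factors 1 rose and 1 fell (1 and 6 adjusted over the list alone), with a shift of -0.32 (adjusted p = 0.019; adjusted p = 0.38 with an estimated correlation), a call that ended without day 7 MC221 (-0.34). Markers of endothelial (adjusted p = 0.37) and myeloid cells (adjusted p = 0.79) did not pass, and of the mesangial and smooth muscle markers Acta2 rose 5.55-fold.

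Of the 834 genes that were higher, 824 lay above 4 times the carry-over share of 0.581%, and 625 reached at least the TdTomato level; Thbs4 was 1 of the 10 within it. The plot of the rise in EGFP against the rise in TdTomato gives the distribution. With each of the 3 slides that hold day 7 mice held out, 84.8% to 96.7% of the genes called on the others moved the same way on it. With the slide as a block 1436 genes were higher and 1165 lower. Fitm1 lost its call without day 0 MC731, day 7 MC824 or day 7 MC943 (-1.63 to -1.61).

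**Figure D2:**
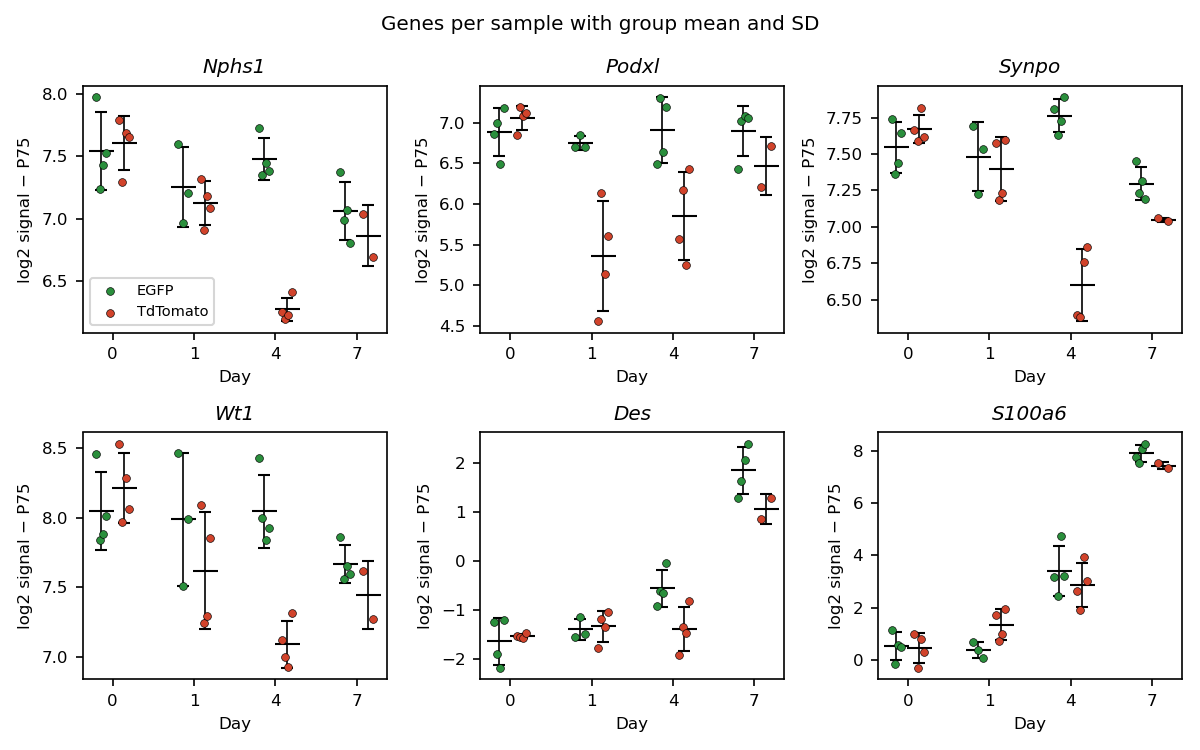
Each point is the log2 signal relative to the array's 75th percentile (y axis) of 1 gene on 1 array, by day (x axis) and population, with the mean and SD of each group, for Nphs1, Podxl, Synpo, Wt1, Des and S100a6. Nphs1 in TdTomato goes from 7.61 at day 0 to 6.27 at day 4 and 6.86 at day 7, and S100a6 reaches 7.92 in EGFP and 7.44 in TdTomato at day 7.

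**Figure D3:**
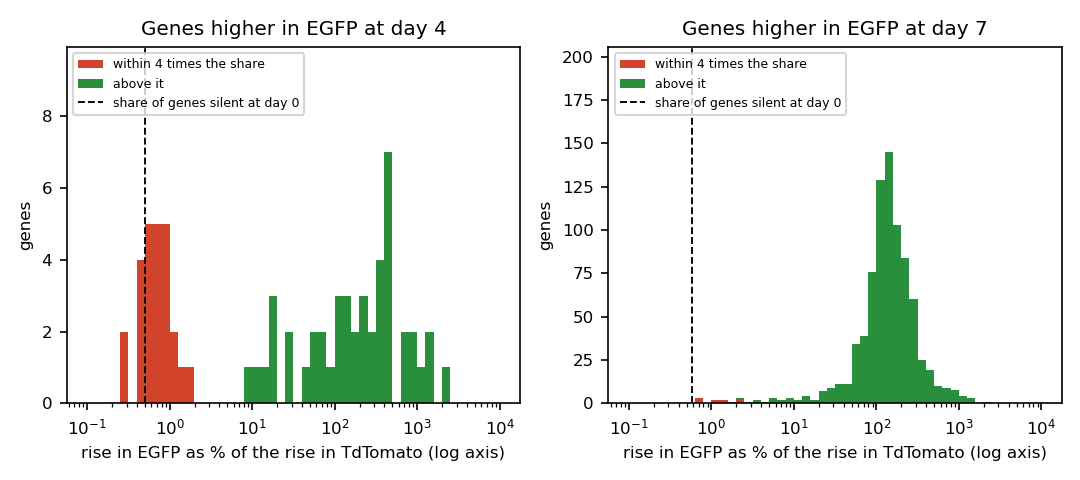
Histograms of the rise in EGFP as a percentage of the rise in TdTomato (x axis, log scale) for genes called higher in EGFP, at day 4 (71 of 87 genes drawn) and day 7 (818 of 834), with the y axis giving the number of genes. The line marks the share of 0.495% at day 4 and 0.581% at day 7, and the genes without a rise in TdTomato, 16 at each day, are not drawn.

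In TdTomato podocytes, the transcriptome had been rebuilt by day 1, with 3725 genes higher and 4366 lower (n = 4 and 4) around a median of all genes of -0.13. Podxl, the main sialoprotein of the foot process surface, fell 3.24-fold (-1.70 ± 0.28, adjusted p = 1.9e-05), Nphs1 fell by 0.48 ± 0.17 and Wt1 by 0.59 ± 0.21. Synpo (-0.28 ± 0.14, adjusted p = 0.10) and Des (0.20 ± 0.26) did not pass. Genes dim or below background at day 0 rose far, among them Psors1c2 2922-fold (above background on 1 of 4 day 0 arrays), Epha8 at least 874-fold, the desmosomal protein Pkp1 at least 525-fold, the Notch ligand Dner at least 319-fold and the hedgehog effector Gli1 at least 286-fold. Among the falls were Vat1l (at least 4.47-fold), the succinate receptor Sucnr1 (9.60-fold, -3.26 ± 0.61), Mnd1 (8.90-fold) and the lipase Mgll (8.45-fold).

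The NF-kB and chemokine genes stood out at day 1, with 21 of 29 higher and 2 lower, as many adjusted over the list alone. Cxcl16 rose 284-fold (8.15 ± 0.46), the adhesion molecule Icam1 201-fold (7.65 ± 0.56), Cxcl10 53.8-fold and Tnf at least 17.0-fold. The list shifted by 3.07 (adjusted p = 5.3e-08; adjusted p = 0.93 with an estimated correlation), with slide medians from 2.55 to 3.38. Translation factor and ribosome biogenesis genes had 16 of 32 higher and 2 lower (17 and 2 adjusted over the list alone), led by the nucleolar genes Gnl3 (13.1-fold) and Nop58 (8.68-fold). They shifted by 0.72 (adjusted p = 0.00028; adjusted p = 0.99 with an estimated correlation). Immediate early genes had 11 of 30 higher and 5 lower, with Gem up 161-fold and Myc at least 36.3-fold, and did not pass as a list (adjusted p = 0.18). Slit diaphragm genes went both ways, 5 of 35 higher and 15 lower (adjusted p = 0.22), as did podocyte transcription factors, 5 of 18 higher and 10 lower, with Tcf21 down 3.06-fold and Zhx2 up 10.3-fold. Unfolded protein response (3 of 26 higher, 14 lower, adjusted p = 0.068, past the test with the mouse as a random block at -0.63 and without day 0 MC122 or day 1 MC542 at -0.73 to -0.72) did not pass as a list. Heat shock (2 of 17 higher, 11 lower, adjusted p = 0.18), cholesterol synthesis (3 of 25 higher, 13 lower, adjusted p = 0.096) and oxidative stress genes (6 of 19 higher, 10 lower, adjusted p = 0.28) did not pass. Of the markers of other cells, 6 of 22 myeloid markers rose, with Aif1 at least 52.2-fold up (adjusted p = 0.088 for the list, which passed without day 1 MC541 at 1.07), and 0 of 23 endothelial markers rose.

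With each slide held out, 97.1% to 99.1% of the genes called on the others moved the same way on it, and with the slide as a block 4354 were higher and 5351 lower. The calls of Nphs1 and Wt1 ended without day 0 MC122 or day 1 MC541, and that of Wt1 also without day 1 MC542 (-0.42 to -0.41 for Nphs1 and -0.48 to -0.47 for Wt1).

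At day 4 the TdTomato podocytes had 3347 genes higher and 5611 lower (n = 4 and 4) around a median of all genes of -0.29. At 2-fold or more the balance turned, with 2633 higher and 1627 lower. Of 35 slit diaphragm and foot process genes 0 rose and 28 fell, as many adjusted over the list alone, among them Nphs1 (2.52-fold, -1.33 ± 0.17, adjusted p = 5.4e-07), Thsd7a (2.75-fold) and Sema3g (2.66-fold). The list shifted by -0.64 (adjusted p = 9.4e-06; adjusted p = 0.29 with an estimated correlation), with slide medians from -0.78 to -0.51. Synpo fell 2.11-fold (-1.07 ± 0.14), Podxl 2.30-fold (-1.20 ± 0.28) and Wt1 2.17-fold (-1.12 ± 0.21), while Des (0.14 ± 0.26) did not pass. Of 18 podocyte transcription factors 12 fell and 1 rose, among them Foxd2 (2.73-fold down) and Foxc1 (2.63-fold down), for a shift of -0.71 (adjusted p = 0.026; adjusted p = 0.52 with an estimated correlation). Heat shock genes had 11 of 17 lower and 0 higher, with the chaperone Hspa1a down 6.10-fold, and shifted by -0.70 (adjusted p = 0.016; adjusted p = 0.70 with an estimated correlation), a call that ended with quantile scaling.

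The rises at day 4 covered cell cycle, injury and inflammation. Of 34 cell cycle genes 18 rose and 4 fell, as many adjusted over the list alone, with the mitotic genes Birc5 (370-fold, 8.53 ± 0.27), Nusap1 (85.2-fold) and Bub1b (52.9-fold), for a shift of 1.12 (adjusted p = 6.9e-05; adjusted p = 0.29 with an estimated correlation). Of 23 injury markers 13 rose and 3 fell, with the transcription factor Snai2 (15.0-fold) and the hyaluronan receptor Cd44 (9.63-fold), for a shift of 1.59 (adjusted p = 0.005; adjusted p = 0.42 with an estimated correlation). Of 29 NF-kB and chemokine genes 15 rose and 2 fell, with Cxcl16 at 551-fold and Ccl5 at 167-fold, for a shift of 1.80 (adjusted p = 1.9e-05; adjusted p = 0.52 with an estimated correlation). Growth factors and receptors had 11 of 36 higher and 6 lower, with neuregulin Nrg1 at least 339-fold and endothelin Edn1 350-fold up, and shifted by 1.07 (adjusted p = 0.038; adjusted p = 0.70 with an estimated correlation). That call ended with quantile scaling or the slide as a block and without day 0 MC731 or MC753 or day 4 MC822 or MC823 (0.44 to 0.89). As single genes, Epha8 rose at least 6086-fold, Thbs4 at least 5615-fold, P2rx7 3939-fold (11.94 ± 0.40), Col22a1 at least 809.7-fold and the placental prolactin-family gene Prl2a1 at least 669-fold, and the largest falls were of the histamine receptor Hrh1 (8.17-fold), Rufy4 (7.54-fold) and Creg2 (6.54-fold).

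Markers of other cell types moved at day 4 beside these groups. Of 22 myeloid markers 10 rose and 0 fell, with the complement gene C1qa (at least 15.6-fold) and Aif1 (at least 34.3-fold), for a shift of 2.08 (adjusted p = 0.00031; adjusted p = 0.52 with an estimated correlation). Of 10 lymphocyte markers 5 rose and 1 fell, with the B cell receptor gene Cd79b at least 35.7-fold up, for a shift of 1.67 (adjusted p = 0.023; adjusted p = 0.70 with an estimated correlation). Endothelial markers had 6 of 23 higher and a shift of 1.41 that did not pass (adjusted p = 0.085) unless day 0 MC742, day 4 MC151 or day 4 MC692 was left out (1.66 to 2.16), and distal nephron markers (adjusted p = 0.086) did not pass. Of 5038 genes above background on no day 0 array, 501 were above background on all 4 TdTomato arrays at day 4, against 193 at day 1 and 270 at day 7 (n = 2). On all EGFP arrays 1, 5 and 19 were, at days 1, 4 and 7. With each slide held out, 97.9% to 98.8% of the genes called on the others moved the same way on it, and with the slide as a block 3849 were higher and 6838 lower.

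At day 7 TdTomato rests on 2 arrays, and 1704 genes were higher and 1323 lower around a median of all genes of -0.14. S100a6 rose 127-fold (6.99 ± 0.52), Timp1 41.6-fold (5.38 ± 0.40), Clu 13.3-fold and Des 6.04-fold (2.59 ± 0.32, adjusted p = 2.3e-06). Of 23 injury markers 12 rose and 0 fell (17 adjusted over the list alone), for a shift of 2.24 (adjusted p = 2.7e-10; adjusted p = 0.0078 with an estimated correlation). Of 35 slit diaphragm genes 15 fell and 0 rose (19 adjusted over the list alone), for a shift of -0.38 (adjusted p = 9.2e-05; adjusted p = 0.19 with an estimated correlation). Sema3g was down 3.60-fold, Nphs1 down 1.67-fold (-0.74 ± 0.21, adjusted p = 0.013) and Synpo and Wt1 lower by 0.62 and 0.77 on the log2 scale (-0.62 ± 0.17 and -0.77 ± 0.26). Podxl (-0.59 ± 0.35, adjusted p = 0.24) did not pass. Thbs4 rose at least 2863-fold, Crct1 2005-fold, P2rx7 1718-fold and Epha8 at least 531-fold. Among the falls were Opcml (at least 4.35-fold), Slc16a9 (6.51-fold), Dnal1 (at least 2.31-fold) and Adra2c (4.39-fold).

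Inflammatory, cell cycle and matrix lists were up in TdTomato at day 7. NF-kB and chemokine genes had 16 of 29 higher (19 adjusted over the list alone) and a shift of 1.74 (adjusted p = 2.7e-10; adjusted p = 0.17 with an estimated correlation), with Cxcl16 up 44.7-fold and Icam1 28.0-fold. Focal adhesion and actin genes had 15 of 40 higher and 1 lower (15 and 2 adjusted over the list alone; adjusted p = 1.3e-06; adjusted p = 0.19 with an estimated correlation). TGF-beta and extracellular matrix genes had 15 of 36 higher and 1 lower (16 and 1 adjusted over the list alone; adjusted p = 2e-07; adjusted p = 0.19 with an estimated correlation). Growth factors and receptors had 14 of 36 higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 5e-05; adjusted p = 0.19 with an estimated correlation). Cell cycle genes had 10 of 34 higher (14 and 1 lower adjusted over the list alone) and a shift of 0.84 (adjusted p = 3.6e-06; adjusted p = 0.17 with an estimated correlation), with Nusap1 up 36.9-fold and Birc5 15.0-fold. Interferon-stimulated genes had 10 of 31 higher (12 adjusted over the list alone; adjusted p = 0.0003; adjusted p = 0.28 with an estimated correlation). MHC class I and antigen presentation genes (2 of 15 higher, 2 lower, adjusted p = 0.43) did not pass. Podocyte transcription factors had 7 of 18 lower and 1 higher (shift -0.31, adjusted p = 0.036; adjusted p = 0.32 with an estimated correlation), a call that ended with the slide as a block, a strict filter or the authors' values, and without day 0 MC742 or day 7 MC221 (-0.28 to -0.24).

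Markers of other cells rose with these groups at day 7. Of 23 endothelial markers 15 rose and 0 fell (19 and 1 adjusted over the list alone), with the transcription factor Sox18 up 17.5-fold (4.13 ± 1.14), for a shift of 3.31 (adjusted p = 4.8e-07; adjusted p = 0.32 with an estimated correlation) and slide medians of 2.33 and 4.94. Of 22 myeloid markers 8 rose (9 adjusted over the list alone), with C1qa at least 5.25-fold up (adjusted p = 0.00013; adjusted p = 0.28 with an estimated correlation). Of 10 lymphocyte markers 4 rose, with Cd79b at least 17.1-fold up (adjusted p = 0.00062; adjusted p = 0.28 with an estimated correlation). Parietal epithelial markers had 5 of 13 higher and 2 lower, with the stem cell marker Prom1 up 19.3-fold (adjusted p = 0.015; adjusted p = 0.28 with an estimated correlation). Mesangial markers (5 of 19 higher, shift 0.95, adjusted p = 0.013; adjusted p = 0.52 with an estimated correlation) lost their call without MC791 (-0.02). Markers of the distal nephron (3 of 15 higher, shift 2.05, adjusted p = 0.011; adjusted p = 0.38 with an estimated correlation) and of erythrocytes and platelets (3 of 8 higher, shift 1.69, adjusted p = 0.015; adjusted p = 0.32 with an estimated correlation) lost theirs without MC221 (0.29 and 0.36), and the distal nephron call also ended with the mouse as a random block (1.28).

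With either slide of the day 7 TdTomato arrays held out, 98.5% and 93.5% of the genes called on the others moved the same way on it, and with the slide as a block 2250 genes were higher and 2729 lower. Normexp background correction gave 1351 higher and 1689 lower, a 2-fold threshold 1573 and 223, and only the groups compared 1475 and 372. Leaving out MC221 gave 1464 genes (1075 and 389) and leaving out MC791 gave 1502 (999 and 503), each with 1 array left that is assumed to vary like the other groups. The call of Sox18 ended without either array (3.63 to 4.62), as did those of Synpo (-0.63 to -0.61) and Wt1 (-0.94 to -0.59), the last also without day 0 MC122 or MC742. Without MC791 the calls of Nphs1 (-0.57) and Opcml (-2.73) ended, and without MC221 that of Slc16a9 (-2.18). The 2 MC221 columns of the authors' processed table do not match their scanner files, as described with the processing.

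**Figure D4:**
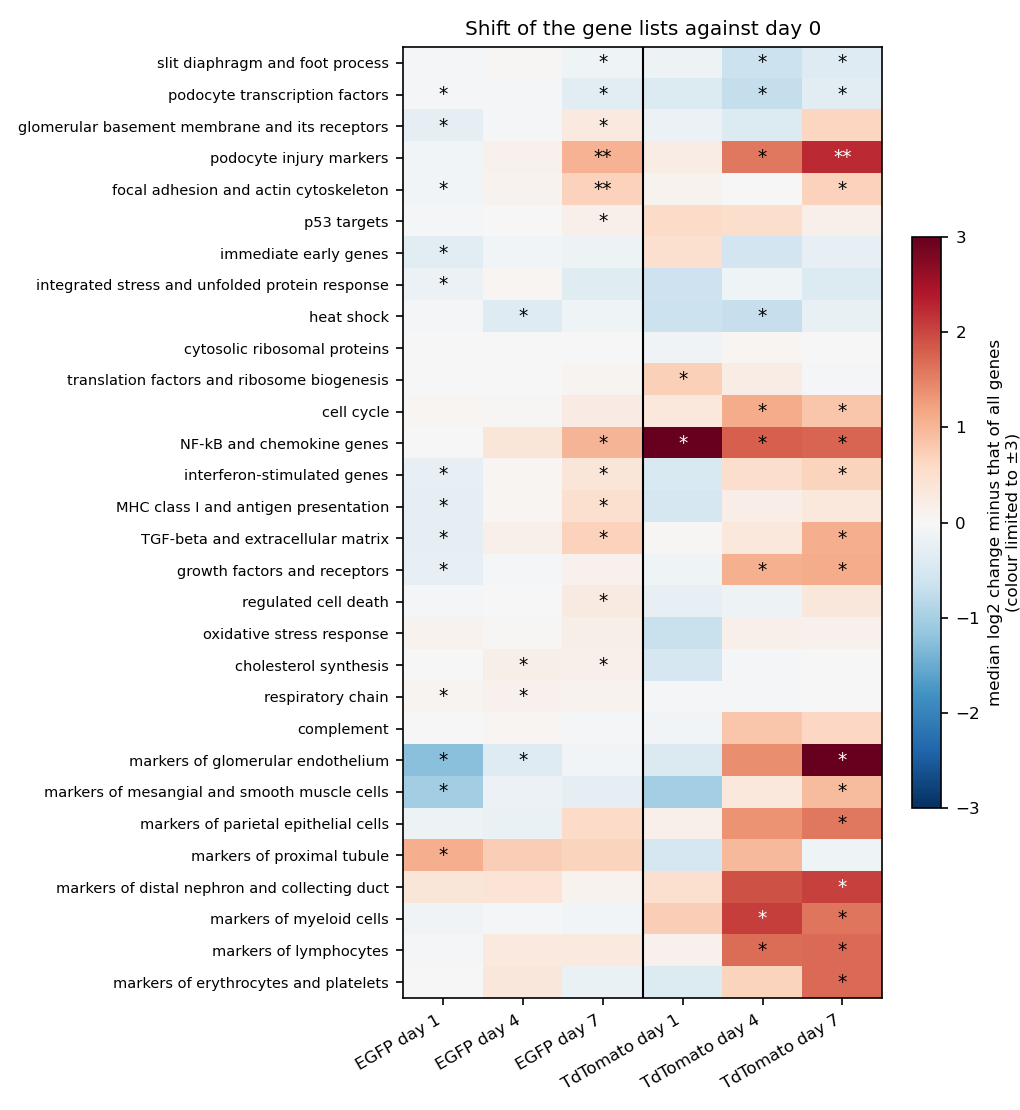
Heat map of 30 gene lists (y axis) in the 6 comparisons of a later day with day 0 (x axis), with colour for the list's median log2 change relative to all genes. 1 star marks a camera adjusted p under 0.05 at the preset correlation and 2 stars mark lists that also passed with an estimated correlation, which are the injury markers in both populations at day 7 (1.04 and 2.24) and the focal adhesion genes in EGFP at day 7 (0.68).

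The comparison of both populations on the same day asks how targeted and untargeted podocytes differ. At day 1 TdTomato had 3709 genes higher and 3999 lower than EGFP (n = 4 and 3), around a median of -0.03. NF-kB and chemokine genes were higher in 20 of 29 and lower in 1, by a shift of 3.18 (adjusted p = 2.9e-08; adjusted p = 0.86 with an estimated correlation), with Icam1 157-fold and Cxcl16 120-fold higher. Immediate early genes were higher in 12 of 30 and lower in 2 (shift 0.59, adjusted p = 0.013; adjusted p = 0.99 with an estimated correlation). Translation factor genes were higher in 17 of 32 and lower in 2 (shift 0.54, adjusted p = 0.0005; adjusted p = 0.99 with an estimated correlation). Among the differences were those of Gng4 (at least 92.8-fold), Prl2a1 (at least 72.3-fold) and Cdh22 (at least 92.9-fold) upward and of Vat1l (at least 8.09-fold) and Sucnr1 (13.6-fold) downward. Myeloid markers were higher in 6 of 22, with Aif1 at 84.0-fold (adjusted p = 0.039; adjusted p = 0.99 with an estimated correlation). That call ended with the mouse as a block (0.28), with the slide as a block and without EGFP MC125 (0.67) or TdTomato MC831 (0.28).

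At day 4 TdTomato had 3284 genes higher and 6032 lower than EGFP (n = 4 and 4), around a median of -0.33. At 2-fold or more 2633 were higher and 2069 lower. Slit diaphragm genes were lower in 30 of 35 and higher in 0, by a shift of -0.74 (adjusted p = 9.8e-06; adjusted p = 0.36 with an estimated correlation). Cell cycle genes were higher in 18 of 34 and lower in 5 (shift 1.00, adjusted p = 0.00012; adjusted p = 0.36 with an estimated correlation), with Birc5 101-fold and Nusap1 74.0-fold higher. NF-kB and chemokine genes were higher in 14 of 29 and lower in 3 (adjusted p = 6.2e-05; adjusted p = 0.69 with an estimated correlation). Among single genes were the protease inhibitor Spink2 at least 104-fold, the cytokine Il31 321-fold and Prl7b1 at least 64.3-fold higher, and Cldn17 (4.96-fold), Igsf1 (4.72-fold) and Olfr1251 (at least 2.11-fold) lower. Endothelial markers were higher in 14 of 23 and lower in 2 (shift 2.57, adjusted p = 0.0026; adjusted p = 0.79 with an estimated correlation). Myeloid markers were higher in 11 of 22 (shift 2.07, adjusted p = 9.8e-05; adjusted p = 0.69 with an estimated correlation). Proximal tubule markers were higher in 4 of 25 (shift 2.06, adjusted p = 0.019; adjusted p = 0.79 with an estimated correlation), the last not without TdTomato MC823 (0.40).

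At day 7 TdTomato (n = 2) had 967 genes higher and 125 lower than EGFP (n = 4), around a median of -0.18. Endothelial markers led, with 17 of 23 higher and 0 lower (20 adjusted over the list alone) and a shift of 3.97 (adjusted p = 5.6e-15; adjusted p = 0.28 with an estimated correlation), slide medians of 3.86 and 5.04, and Sox18 at least 21.4-fold higher, a call that ended without TdTomato MC791 (4.98). Cell cycle genes were higher in 7 of 34 (13 adjusted over the list alone), by a shift of 0.36 (adjusted p = 0.00015, and adjusted p = 0.28 with an estimated correlation). Nusap1 was among them (log2 4.32 ± 0.40, above background on 2 of 4 EGFP arrays). Growth factors and receptors were higher in 6 of 36 (adjusted p = 0.001; adjusted p = 0.46 with an estimated correlation). Other cell markers were higher too. Myeloid markers were so in 6 of 22 (9 adjusted over the list alone; shift 1.66, adjusted p = 1.9e-07; adjusted p = 0.28 with an estimated correlation). Lymphocyte markers were higher in 2 of 10 (4 adjusted over the list alone; shift 1.25, adjusted p = 0.001; adjusted p = 0.46 with an estimated correlation). Those of erythrocytes and platelets were higher in 2 of 8 (shift 2.22, adjusted p = 0.001; adjusted p = 0.30 with an estimated correlation). Distal nephron markers (2 of 15 higher, shift 1.56, adjusted p = 0.002; adjusted p = 0.49 with an estimated correlation) lost their call with the mouse as a block (0.38) or without TdTomato MC221 (0.35). Mesangial markers (2 of 19 higher, shift 1.12, adjusted p = 0.0029; adjusted p = 0.78 with an estimated correlation) lost theirs without TdTomato MC791 (0.01). Parietal (2 of 13 higher, 1 lower, adjusted p = 0.28) and proximal tubule markers (2 of 25 higher, adjusted p = 0.14) did not pass; the latter did with normexp or the slide as a block (0.41 and 0.52), and without EGFP MC824 or TdTomato MC791 (0.97 and 1.42). No slit diaphragm gene was called, at a list shift of -0.13 (adjusted p = 0.013; adjusted p = 0.55 with an estimated correlation) that lost its call without TdTomato MC221 (-0.08) or with quantile scaling. Prl2a1 was at least 91.6-fold, Ripk4 155-fold and the chemokine receptor Ccr6 at least 63.0-fold higher, and Dlx4 was 3.29-fold lower, a call that ended without TdTomato MC791 (-1.37).

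With the slide as a block the 3 counts were 9226, 10888 and 2229 (1339 higher and 890 lower at day 7), and with the mouse as a block, for pairs from the same animal, 9506, 11480 and 1689 (1168 higher and 521 lower). With each slide held out, 94.5% to 99.4% of the genes called on the others moved the same way on it. Normexp background correction gave 803 higher and 523 lower at day 7 and the authors' values 1281 and 647, and leaving out TdTomato MC791 or MC221 gave 532 or 617 genes.

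**Figure D5:**
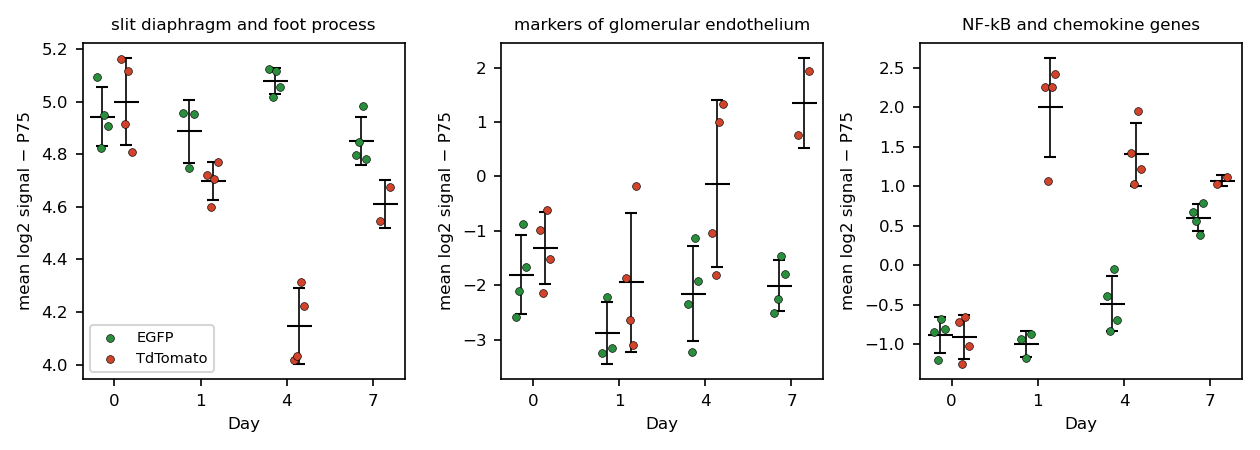
Each point is the mean log2 signal (y axis) of a gene list on 1 array, by day (x axis) and population, for slit diaphragm genes, NF-kB and chemokine genes and endothelial markers. The slit diaphragm mean in TdTomato is 5 at day 0 and 4.15 at day 4, the NF-kB mean 1.999 at day 1 and 1.07 at day 7, and the 2 TdTomato arrays of day 7 have endothelial means of 0.76 and 1.94 against -2.52 to -1.45 in EGFP.

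Whether the change from day 0 differed between the populations was tested as an interaction. It differed for 6004 genes at day 1 (2867 more positive in TdTomato, 3137 more negative), 6932 at day 4 (2503 and 4429) and 420 at day 7 (414 and 6). At 2-fold or more the day 4 genes were 2209 and 1984. No size is given for genes above background on no array of a compared group. At day 1 Gng4 and Ptprn were among the genes with the higher change in TdTomato, and Vat1l and Sucnr1 (-3.61 ± 0.90) among those with the lower. NF-kB and chemokine genes responded more in TdTomato in 19 of 29 and less in 1 (shift 3.26, adjusted p = 5.5e-09; adjusted p = 0.70 with an estimated correlation). So did immediate early genes in 10 of 30 (adjusted p = 0.013) and translation factor genes in 17 of 32 (adjusted p = 0.00047), both with adjusted p = 0.99 with an estimated correlation. Podxl fell more in TdTomato (-1.56 ± 0.42).

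At day 4 the response of slit diaphragm genes was lower in TdTomato for 26 of 35 and higher for 0 (29 adjusted over the list alone; shift -0.72, adjusted p = 2.7e-06; adjusted p = 0.28 with an estimated correlation). Nphs1 differed by -1.27, Synpo by -1.29 and Wt1 by -1.12. Cell cycle genes responded more in TdTomato in 15 of 34 and less in 2 (shift 1.01, adjusted p = 6e-05; adjusted p = 0.28 with an estimated correlation). So did NF-kB genes in 14 of 29, with less in 2 (shift 1.30, adjusted p = 3.1e-05; adjusted p = 0.70 with an estimated correlation), and myeloid markers in 7 of 22 (shift 1.96, adjusted p = 0.00029; adjusted p = 0.70 with an estimated correlation). Tmem151b and Kcnmb3 had the higher change in TdTomato, while Crct1 (adjusted p = 0.011) and Igsf1 (-2.17 ± 0.50) had the lower. Des, not called in either population at day 4, also passed this test with the higher change in EGFP (-0.93).

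At day 7 the endothelial markers differed most (shift 3.50, adjusted p = 2.2e-11; adjusted p = 0.42 with an estimated correlation), with 0 of 23 members called by limma over all genes and 16 adjusted over the list alone. Cell cycle genes responded more in TdTomato in 3 of 34 (adjusted p = 5.2e-05; adjusted p = 0.42 with an estimated correlation), led by Nusap1 (4.84 ± 0.52). Slit diaphragm genes shifted by -0.18 with 0 called (adjusted p = 0.0037; adjusted p = 0.42 with an estimated correlation), a call that ended with quantile scaling. Prl2a1 and Ripk4 were among the genes with the higher change in TdTomato. With the slide as a block the 3 counts were 7857, 9188 and 844 (691 and 153), with the mouse as a block 8412, 10038 and 705 (632 and 73), and at day 7 normexp background correction gave 172 and 1.

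How far both populations changed the same genes was counted. At day 4, 57 genes were higher in both, 4 were lower in both and 1 went opposite ways. At day 7, 514 were higher in both, 203 lower in both and 6 went opposite ways. If the calls in both populations were independent, 18.6 higher and 2.15 lower in both would be expected at day 4, and 90.9 and 25.4 at day 7. Both populations came largely from the same mice, so the overlaps were not tested. Across all genes, which are not independent replicates, the correlation of both changes was 0.119, 0.368 and 0.529 at days 1, 4 and 7. Both changes share their mice and day 0 slides, and with disjoint mice its median was -0.02, 0.217 and 0.367, with a range of 0.099 to 0.384 at day 4. These splits use fewer arrays, which can lower a correlation. The covariance of both changes was 0.063, 0.265 and 0.402 with all mice, and its median with disjoint mice was -0.016, 0.198 and 0.340.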

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

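The carry-over tests on all genes higher in EGFP, the test for genomic DNA, the tests for other cells in the sort and the splits that move the day between mice were chosen after the results were seen. The other tests were written down before their own values were seen, though after the gene counts were known. The comparisons, gene lists and naming rule were fixed before the data were examined. Looking at 222 groups of values, 11 held a sample far from its group, and chance alone gives about 1 in 20 groups. Mouse MC753 had distal nephron markers at -2.57 in EGFP at day 0. In EGFP at day 7 MC221 had Podxl at 6.436, immediate early genes at 3.194 and growth factors at -1.214. In TdTomato the stress response stood at 3.377 in MC742 at day 0 and 2.201 in MC125 at day 1, where ribosomal proteins stood at 6.934 and the respiratory chain at 5.617. MC541 at day 1 had cell cycle genes at -2.098 and NF-kB genes at 1.069. At day 4 MC823 had proximal tubule markers at 2.107.

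The response differed between the populations in 6004, 6932 and 420 genes at days 1, 4 and 7, which drew attention as differences between groups. At day 1 these were Podxl (-1.564), immediate early genes (0.701), translation factors (0.621) and NF-kB genes (3.264). At day 4 they were Nphs1 (-1.27), Podxl (-1.225), Synpo (-1.292), Wt1 (-1.116), Des (-0.932), slit diaphragm genes (-0.721), podocyte transcription factors (-0.744), cell cycle (1.01), NF-kB (1.295), growth factors (1.028), respiratory chain (-0.202), endothelial (2.021), myeloid (1.957) and lymphocyte markers (1.686). At day 7 they were slit diaphragm genes (-0.183), cell cycle (0.696), growth factors (0.96), respiratory chain (-0.074), and markers of endothelium (3.501), mesangium (1.184), distal nephron (1.195), myeloid cells (1.423), lymphocytes (1.196) and erythrocytes (1.876). The lists passed camera at the preset correlation only, and the lowest adjusted p with an estimated correlation was 0.28. With quantile scaling the day 4 calls of podocyte transcription factors (-0.514), growth factors (0.735), the respiratory chain (0.037), endothelial (1.876) and lymphocyte markers (1.521) ended, as did the day 7 calls of slit diaphragm genes (-0.1) and the respiratory chain (0.062). With the mouse as a block those of podocyte transcription factors (-0.745), growth factors (1.028) and day 7 distal nephron markers (0.545) ended. At day 7 erythrocyte markers lost their call without TdTomato MC221 (0.511) and mesangial markers without TdTomato MC791 (0.261). Probes without a symbol were not tested as genes, and 6, 26 and 369 of them changed in EGFP and 4334, 5929 and 1088 in TdTomato at days 1, 4 and 7.

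Chance division of the samples into later days and day 0 was tested with 35 splits that ignore the slide. No share under 1 of 35 can arise, and there was no adjustment for the number of comparisons. Within that limit, only 1 of 35 splits, the real one, gave as many genes in EGFP at days 1, 4 and 7 (4, 93 and 1134, highest other 1, 0 and 1) and in TdTomato at days 1 and 4 (8091 and 8958, highest other 4519 and 455). The EGFP count of 4 at day 1 fell to 0 without day 0 MC731, day 0 MC742 or day 1 MC542, so chance is not excluded there. Exchanging days only within slides leaves 8, 8 and 12 of these splits in EGFP and 8 and 8 in TdTomato, too few for a share under 0.05, with highest others of 0, 0, 0, 3154 and 1. The split with 4519 groups TdTomato MC541 of day 1 with 3 day 0 arrays and day 0 MC122 with the other day 1 arrays. At day 0 all 35 of 35 splits gave as many as the 0 genes between the populations, which is certain for a count of 0 and decides nothing. At days 1 and 4 only 1 of 35 did (7708 and 9316, highest other 7402 and 852), and among the 8 splits parting as many pairs the highest were 4421 and 1. The split with 7402 puts TdTomato MC541 with the EGFP arrays. For the interactions 11 of 100 and 6 of 100 splits that swap populations within mice gave as many as 6004 and 6932 (highest other 6139 and 7344). By its share this test does not exclude chance. Apart from the real one, all of these swap day 0 pairs alone or, at day 4, all later pairs, and 0 genes were called between the populations at day 0. Such swaps leave the later difference between the populations whole, so the share cannot decide about chance. Among the splits not of this kind the highest count was 0 at both days. Moving the day between mice gave 1 of 35 at both days, with a highest other of 1. Day 7 TdTomato, with 2 arrays, was not split.

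A small EGFP response at days 1 and 4 could be TdTomato RNA carried over in the sort, or a response of the EGFP cells. At day 1, 0% of the called genes rose by over 4 times the share, but all 4 had their highest ratio in MC542 (share 0.558%) and 0 in MC125, where the share was highest (0.644%), and in MC541 the share was -0.051% at a median ratio of 0.650%. At day 4 71.26% and at day 7 98.8% rose by more (71.3% and 98.7% with called genes kept in the reference, at shares of 0.498% and 0.757%), so carry-over of that share is too small for them, and 48 and 625 genes reached the TdTomato level. For the 25 day 4 genes within the share, 8% had their highest ratio in the mouse with the highest share, under the 40% set before as speaking against carry-over. Neither day 1 nor the 25 genes of day 4 are settled, because few reference genes were well above background in EGFP. Per mouse these were only 8% to 36% at day 1 and 1.69% to 13.6% at day 4. The highest, 36% and 13.6%, belonged to MC542 and MC692. In these mice all 4 genes of day 1 and 13 of the 25 of day 4 had their highest ratio. The share and the detection of reference genes thus rank the mice differently, and the ratios per mouse cannot decide. The day 7 share has the same limit and rests on 16 reference genes. Of these 6.25% were well above background in EGFP in MC221 and 0% in MC791, at shares of 0.860% and 0.002%.

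Genes silent at day 0 that came on in TdTomato at day 4 could reflect genomic DNA or a higher background, the scaling, or single probes that bind other RNA. Of the silent genes 70.05% were above background on no TdTomato array at day 4, past the bound set against a general rise. A small rise would also leave most silent genes below the cutoff, so this test cannot exclude it. On at least 1 array at day 4, 1509 silent genes were above background in TdTomato and 575 in EGFP. After quantile normalization 99.8% of the genes that came on were still higher, but it moved the median change only from -0.286 to -0.293, so scaling stays open. A further probe existed for 60 of the 501 genes, and it rose by at least 1 log2 in 43 (71.67%); single probes stay untested for the others.

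Endothelial markers in TdTomato at day 7 might be part of the general rise of dim genes, or endothelial cells in the sort, or their expression by podocytes. Their median lay at percentile 100 of matched random lists. Those lists hold genes drawn independently, while the estimated correlation within the endothelial list was 0.635. An extreme percentile can therefore also come from variation that the markers share between samples. Proximal tubule markers in EGFP reached percentile 100 too at days 1 and 4, with 0 and 1 of their dim markers called higher. Of the dim endothelial markers in TdTomato at day 7, 73.68% were called, under the 75% set for cells in the sort. That bound was set after the value had been seen, so this test cannot tell. At day 4 the endothelial percentile and share were 100 and 31.58%, but with an SD of 1.54 between the arrays and 14 of 23 markers higher than in EGFP, cells of this type stay open. Myeloid markers at day 4 lay at percentile 96.76, within what the general rise gives, with 50% of the dim markers called, which leaves myeloid cells open too.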

How the results depend on the processing

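The alternatives were set before the data were examined, except that the MC221 and carry-over ones were chosen after the results were seen. The number of genes moved as follows, and the cause was not tested. Normexp background correction gave 0 genes in EGFP at day 1, 55 at day 4 and 173 for the day 7 interaction. The authors' values gave 1928 for TdTomato against EGFP at day 7 and 657 for the day 7 interaction. Both comparisons include the MC221 columns that match no scanner file. Fitting only the groups compared gave 0 in EGFP at day 1, 28 at day 4, and 1847 in TdTomato at day 7. Asking for 2-fold gave 714 in EGFP at day 7, 4939, 4260 and 1796 in TdTomato at days 1, 4 and 7, 4995 and 4702 between the populations at days 1 and 4, and 4193 for the day 4 interaction, fewer by construction. The balance turned at day 4: 2633 higher and 1627 lower in TdTomato, 2633 and 2069 between the populations and 2209 and 1984 for the interaction. The slide as a block gave 277 and 2601 in EGFP at days 4 and 7, 4979 in TdTomato at day 7, 2229 between the populations at day 7 and 844 for the day 7 interaction. The mouse as a fixed term gave 1689 and 705 for the last 2, and the other counts with a mouse block kept their label. Without both MC221 arrays TdTomato at day 7 had 1483 and the populations at day 7 differed in 637. Without genes within the carry-over share EGFP at day 1 had 0. Leaving out 1 sample gave 0 to 6 in EGFP at day 1, 44 to 108 in EGFP at day 4, 1464 to 2632 in TdTomato at day 7 and 532 to 1431 between the populations at day 7.

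Some values or test directions turned. At day 0 between the populations, normexp gave -0.015 for ribosomal and -0.02 for respiratory chain genes, and over the samples left out these ran from -0.038 to 0.15 and from -0.034 to 0.158, and mesangial markers from -0.273 to 0.185. In EGFP at day 1 the respiratory chain stayed above 0 (0.005 to 0.193), and the direction of its test turned without day 1 MC125. Normexp turned Mars2 in TdTomato at day 7 (0.029) and, between the populations at day 7, Dnal1 (0.078) and Igsf10 (0.168), and the mean of probes turned Rpl21 in TdTomato at day 7 (0.141). Signal over background limits the folds of dim genes such as Mars2, Dnal1 and Igsf10.

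Among list results 3355 of 3570 kept their status, called or not called, when a sample was left out, as did 352 of 390 with normexp, 362 of 390 with quantile normalization and 366 of 390 with the slide as a block. Among named genes 9009 of 9578, 938 of 1024, 973 of 1024 and 1016 of 1024 did.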

Other observations

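S100a6 stood at 3.39 in EGFP and 2.88 in TdTomato at day 4 and at 7.92 and 7.44 at day 7, while Nphs1 at day 4 stood at 7.48 and 6.27. The NF-kB and chemokine mean was highest in TdTomato at day 1 (1.999) and lower at day 7 (1.07), and in EGFP it was highest at day 7 (0.60).

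These hypotheses were written after the results were seen. Carry-over may account for the 4 EGFP genes of day 1 (0% above 4 times the share), which mixing known amounts of TdTomato RNA into EGFP RNA would test. Endothelial cells may have entered the TdTomato sort at day 7 (73.68% of dim markers called), which staining sorted cells for an endothelial surface protein would test. A delayed response of EGFP podocytes may follow loss of their neighbours, which a series with fewer targeted podocytes per glomerulus would test. The 98.8% of day 7 genes above 4 times the share bear on carry-over only, not on this hypothesis. Surgery and time since day 0 cannot be told apart from loss of neighbours here.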
